A study of Rhinolophus ferrumequinum with 8 samples.

How the data were processed

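RNA was extracted from whole spleen of wild female greater horseshoe bats, and 8 libraries were prepared by Illumina protocols, per the labels' protocols. The submitters' processing notes name kallisto 0.46.2 and sleuth 0.30.0. The reference transcriptome, the way transcripts were summed to genes and the rescaling between libraries are not given in the sources used here. The deposited table gives 1 value per gene and library as a rescaled TPM signal. Its columns sum to 745098 to 1331820 rather than to 1000000, while the median ratio of each library to the geometric mean over libraries lies between 0.947 and 1.04. The values are therefore treated as a signal comparable between libraries, not as raw TPM. The tests were planned for TPM, and the same log-scale test was used for the rescaled values. Depth is unknown, since the table holds no counts and TPM keeps no step of 1 read, so no counting interval is given.

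All 19652 gene identifiers and names matched the annotation of assembly mRhiFer1_v1.p. The build behind the values is not given in the sources used here, so that annotation served for names and gene spans only and no coordinates are given. Of the genes, 3335 carry only a locus number. Globin, histone, interferon-induced and ribosomal protein genes have near-identical copies that can split reads, so their values are uncertain. Zeros can be failed estimates or real. Each library had 5 to 16 genes at 0 with 8-library means over 10, some, as INS, high in few libraries.

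Genes with a mean of at least 1 over the 8 libraries (13542 genes) were tested on log2(value + 1) with limma 3.58.1 in R 4.3.3 (lmFit, contrasts and eBayes with a trend). All 8 libraries entered 1 fit, and a Benjamini-Hochberg adjusted p under 0.05 was the threshold. The fit had 4 residual and 3.29 prior degrees of freedom. The 4 main comparisons were torpor against summer active, arousal against torpor, winter active against torpor and winter active against summer active. The 2 secondary comparisons were arousal against summer active and winter active against arousal. Of 41 gene lists fixed in advance (stress and hormone responses, cell cycle, blood and immune cell types, other organs, immunity and metabolism), 40 had at least 5 genes tested. Mitochondrially encoded genes were not analysed here. Lists were tested with camera at a preset correlation of 0.01, again with an estimated correlation, and with fry. With the estimated correlation no list passed in any of the 6 comparisons. Of the 40 lists, fry passed only erythroid markers, in the 3 comparisons with summer.

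Genes named in the text follow a rule fixed in advance. In each main comparison it took the 6 largest rises and falls among genes past the threshold with no overlap between the libraries of the states, a mean of at least 5 in the higher state and a real symbol. Where fewer passed, the smallest unadjusted p filled the places. The rule added the 3 members with the smallest p of each list called by camera, and 16 fixed genes where tested, of which CD3E was not. A few genes that the rule took are not reported here. Secondary comparisons took 3 in each direction. Alternatives were a pseudocount of 0.1, no filter, a mean of at least 5, median-of-ratios rescaling, quantile normalization, robust eBayes, a replicate block, only the 2 states compared and leaving out each of the 8 libraries. Rescaling each column to 1000000 and leaving out erythroid and other-tissue list genes were added after the data were seen. In fits without a library, the lone replicate of a state is assumed to vary like the other states.

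In simulated torpor against summer active, 200 of 13542 genes were changed in each of 10 runs. Planted log2 differences of 1, 2 and 3 were called at 9.7%, 74.6% and 89.7%, and 6.84% of calls were false. Camera called a list shifted by 1 in 10 of 10 runs and 0.513% of unshifted lists. This sets no error rate for real lists, whose genes may correlate.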

Results

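Gene expression was measured by RNA sequencing of whole spleen from wild female greater horseshoe bats. The 8 libraries fell into 4 states with 2 biological replicates each, named by state and replicate number, as in torpor 1. Summer active bats were sampled in July. Bats in torpor (the cold, low-metabolism phase of hibernation), arousal and the winter active state were sampled in November, the last 2 states at 2 h and 26 h after capture. The table held 19652 protein-coding genes, of which 13542 had a mean of at least 1 and were tested. The deposited values carry no read counts, so the depth behind each value is unknown. Levels are means ± SD (n = 2 libraries) of rescaled TPM, and a result after rescaling is from columns set to totals of 1000000. Differences are on the log2(value + 1) scale, which understates the change of low genes, and adjusted p-values are limma's for genes and camera's for lists, including those at which a list lost its call. List medians are of log2 differences of members, given also for fits without 1 library where they moved by over 1.5 times, and the level of a list in a library is its median log2 distance from the 8-library mean. In each gene named as a largest rise or fall, both libraries of one state lay above both of the other.

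Replicates correlated least in summer active (r = 0.915 over log2 values of tested genes, against 0.937 in arousal, 0.959 in torpor and 0.959 in winter active). Summer active 1 lay nearer to winter active 1 and torpor 1 (root mean square log2 distances 0.703 and 0.716) than to summer active 2 (0.843). The libraries also differed in transcripts typical of other organs. Albumin (ALB), a hepatocyte product, had values of 12262 in arousal 2, 1077 in summer active 1, 603 in arousal 1 and 378 in torpor 1. It was at most 32.1 in the other 4 libraries. The pancreatic enzyme gene CTRC stood at 363 in torpor 1, 152 in arousal 2 and 81.4 in torpor 2, against 2.19 to 17.2 elsewhere. The adipocyte hormone gene ADIPOQ stood at 81.4 in winter active 2 and 75.4 in arousal 2. S100A8, a neutrophil gene, reached 3214 in torpor 1 against 357 in torpor 2. Keratin KRT4, of squamous epithelium, was at 1617 in summer active 2 and 0.318 in summer active 1. The gastric gene GKN1 was at 666 in winter active 2 and 23.1 in torpor 2. KRT4 and GKN1 were chosen after their values were seen.

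**Figure D1:**
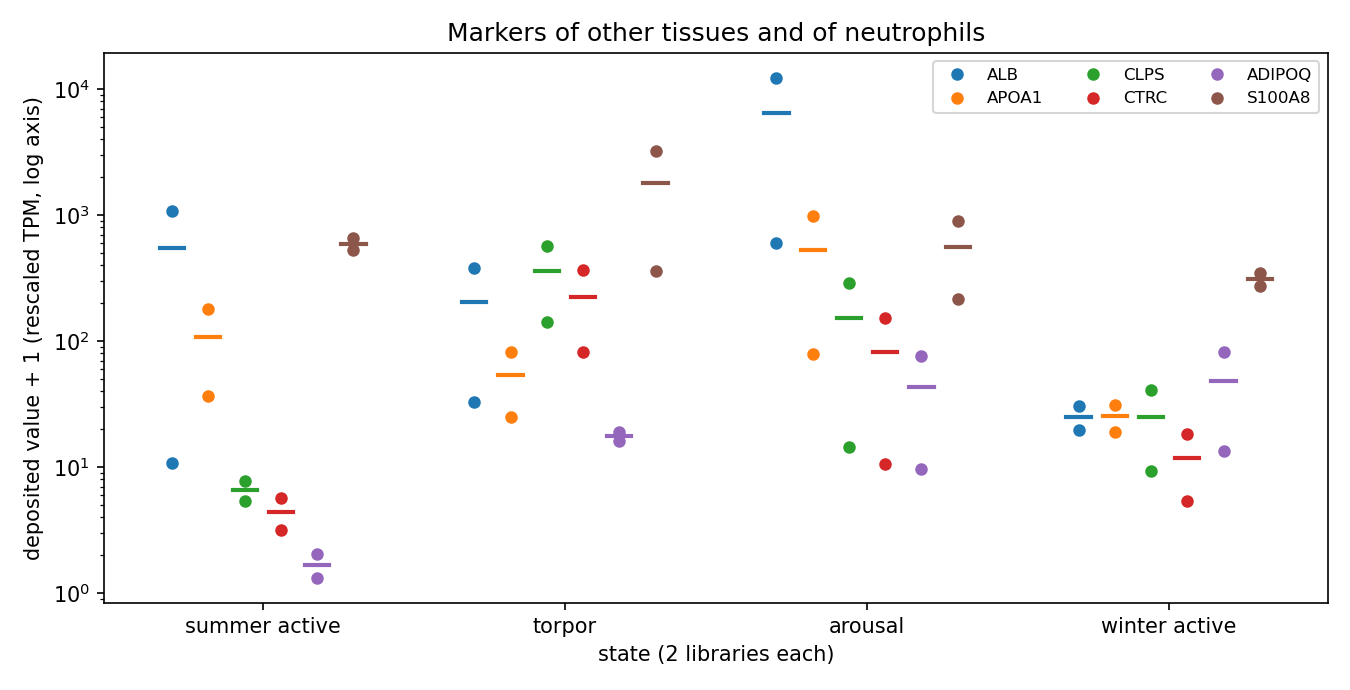
Deposited value + 1 (rescaled TPM, log axis) of 6 genes in the 4 states, with a point for each of the 2 libraries and a bar at their mean. ALB, APOA1, CLPS, CTRC and ADIPOQ mark other organs and S100A8 marks neutrophils, and replicates of a state stood apart, as for ALB at 1077 and 9.78 in summer.

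Torpor against summer active asks how the spleen of hibernating bats differed from that of summer bats. Red blood cell genes fell most among the genes named by the rule. SLC4A1, the red cell anion exchanger (NCBI gene 117013589), stood at 0.426 ± 0.00332 against 235 ± 86.3 (log2 difference -7.32, SE 0.44, adjusted p = 0.0020). AHSP, the alpha-globin chaperone (NCBI gene 117019823), stood at 44.4 ± 29.7 against 3031 ± 731 (log2 difference -6.22, SE 0.62, adjusted p = 0.00986). The embryonic globin HBZ, TMCC2, HEMGN and YPEL4 fell too, with differences of -5.68, -5.17, -4.64 and -4.57 (adjusted p = 0.00124, 0.0020, 0.0048 and 0.0020). B-cell genes fell, with VPREB3 at 23.6 ± 0.301 against 192 ± 6.24 (adjusted p = 0.00218) and CD79B, a chain of the B-cell receptor, at 246 ± 7.9 against 995 ± 112 (adjusted p = 0.0411). Among rises, linker histone H1-4 (NCBI gene 117015308) stood at 18.6 ± 7.94 against 1.47 ± 0.547 (adjusted p = 0.0248) and STEAP1 at 47.5 ± 13.8 against 7.48 ± 0.295 (adjusted p = 0.0282). The cohesin subunit STAG3, the DNA-sensing adaptor STING1 and the acyltransferase LPCAT2 rose by 2.39, 1.91 and 1.35 (adjusted p = 0.0333, 0.0309 and 0.0472). CLPSL2 was at 6.5 ± 2.07 in torpor and listed at 0 in both summer libraries (adjusted p = 0.0229). In all, 76 genes changed, 10 higher and 66 lower. Higher and lower genes numbered 62 and 252 without summer active 1, 0 and 23 without summer active 2, 1 and 30 without torpor 1, 0 and 9 without torpor 2, 8 and 42 without arousal 1, 8 and 46 without arousal 2, and 1 and 34 without either winter active library. The 4 libraries alone gave 11. After rescaling, the all-gene median moved from -0.055 to 0.29 and 20 genes were higher and 36 lower. Of the 15 named genes that passed, the call was lost by 6 with no filter (adjusted p = 0.0525 to 0.0733), 10 in a fit of the 2 states alone (0.0501 to 0.192), 1 under quantile normalization (0.0565), 1 after rescaling (0.0603), 5 without arousal 1 (0.0539 to 0.0828) and 5 without arousal 2 (0.0531 to 0.0795). It was lost by 1 without summer active 1 (0.0606), 8 without summer active 2 (0.0799 to 0.239), 7 without torpor 1 (0.0867 to 0.197), 10 without torpor 2 (0.0581 to 0.255), 5 without winter active 1 (0.0556 to 0.122) and 5 without winter active 2 (0.0532 to 0.119). SLC4A1, HBZ, TMCC2, YPEL4 and VPREB3 kept the call in all 8 fits without a library.

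The lists named here were fixed before the data were examined. Erythroid markers (23 of 23 members, median -3.29) lay lower (adjusted p = 5.31e-28). HBZ, SLC4A1 and EPB42 differed by -5.68, -7.32 and -4.47, and all passed (limma adjusted p = 0.00357 for EPB42), and 11 fell over all genes and 22 adjusted over the list alone. Mitosis genes (31 of 31 members, median -1.40) and S-phase genes (30 of 31, median -0.79), which serve DNA replication, lay lower (adjusted p = 4.93e-18 and 3.13e-08). BIRC5, AURKB and CCNB1 differed by -1.80, -1.78 and -1.56 and GINS3, RRM2 and MCM3 by -1.44, -2.41 and -1.3. Of mitosis and S-phase genes, none fell over all genes but 28 and 3 did adjusted over the list alone. B-cell markers (20 of 21 members, median -1.46) and T-cell markers (23 of 23, median -0.66) lay lower (adjusted p = 2.12e-09 and 3.07e-05). VPREB3, CD79B and SPIB differed by -2.97, -2.01 and -1.38 and CD5, ICOS and IL7R by -1.19, -1.55 and -1.3, of which VPREB3 and CD79B passed. Of B-cell and T-cell markers, 2 and 0 fell over all genes and 15 and 0 adjusted over the list alone. Glucocorticoid-induced genes (16 of 20 members, median -0.45), which respond to stress hormones, lay lower (adjusted p = 0.0377). FAM107A, KLF9 and PER1 differed by -1.15, -2.04 and -1.04, and none fell over all genes but 5 did adjusted over the list alone. None of the 15 lists called here passed with an estimated correlation (adjusted p = 0.762 to 0.785). The erythroid call also passed fry, which tests whether members move one way on balance (adjusted p = 0.0133). The median was -0.71 for glucocorticoid-induced genes without summer active 2, and -1.21 and -0.36 for S-phase genes without summer active 1 and 2. The median was -0.21 for glucocorticoid-induced genes without torpor 2. Glucocorticoid-induced genes lost the call at 0.245 without summer active 1 and 0.176 without torpor 2.

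Interferon-stimulated genes (30 of 37 members, median 0.52), part of antiviral defence, and pattern recognition receptors (22 of 30, median 0.35), which sense microbial molecules, lay higher (adjusted p = 1.46e-05 and 5.10e-04). IFIT2, OASL and IFIH1 differed by 1.71, 1.68 and 0.99 and STING1, IFIH1 and IRAK4 by 1.91, 0.99 and 0.66, of which STING1 passed. Of interferon-stimulated genes and pattern recognition receptors, 0 and 1 rose over all genes and 0 and 1 adjusted over the list alone. Macrophage markers (21 of 24 members, median 0.75) and neutrophil markers (19 of 20, median 1.24) lay higher (adjusted p = 5.69e-05 and 1.58e-04). VCAM1, C1QA and TIMD4 differed by 1.03, 1.54 and 1.31 and BPI and NCF1 by 1.75 and 0.87. Of macrophage and neutrophil markers, no member rose over all genes or adjusted over the list alone. Unfolded protein response genes (17 of 22 members, median 0.11) and chaperones (19 of 25, median 0.17), which help proteins fold, lay higher (adjusted p = 0.0213 and 0.0293). DNAJB11, XBP1 and HSP90B1 differed by 0.73, 0.88 and 0.81 and DNAJA4, DNAJA1 and SERPINH1 by 0.57, 0.90 and 0.97. Of unfolded protein response genes and chaperones, none rose over all genes but 5 and 0 did adjusted over the list alone. Proteasome genes (25 of 33 members, median 0.14), whose products degrade proteins, lay higher (adjusted p = 0.0377). PSMD1, PSMC2 and PSMA5 differed by 0.43, 0.41 and 0.37, and no member rose over all genes or adjusted over the list alone. Against its list, the interferon-stimulated RSAD2, chosen after its values were seen, fell, at 1.12 and 1.48 in torpor against 29.1 and 56.2 in summer (limma adjusted p = 0.0428). The median was 0.17 for unfolded protein response genes without summer active 1, 0.69 for neutrophil markers without summer active 2, and 0.90 and 0.30 for interferon-stimulated genes, 0.74 and 0.052 for pattern recognition receptors, 1.21 and 0.057 for macrophage markers and -0.0061 and 0.29 for chaperones without summer active 1 and 2. The median was -0.0076 for proteasome genes without torpor 1, and -0.12 and 2.46 for neutrophil markers without torpor 1 and 2. Pattern recognition receptors lost the call at 0.0641 without summer active 2, macrophage markers at 0.44 without summer active 2, and neutrophil markers at 0.059 without summer active 2 and 0.931 without torpor 1. Unfolded protein response genes lost the call at 0.129 under quantile normalization and 0.0931 without summer active 1, chaperones at 0.176 under quantile normalization, 0.397 without summer active 1 and 0.060 without torpor 1, and proteasome genes at 0.454 under quantile normalization, 0.111 without summer active 1 and 0.579 without torpor 1.

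Pancreatic markers (14 of 14 members, median 3.96) and adipocyte markers (13 of 14, median 0.79) lay higher (adjusted p = 1.40e-09 and 0.00295). CTRC, SYCN and CLPS differed by 5.35, 5.49 and 5.46 and PLIN1, CIDEA and ADIPOQ by 2.53, 2.88 and 3.41. Of pancreatic and adipocyte markers, none rose over all genes but 13 and 0 did adjusted over the list alone. The median was 0.52 for adipocyte markers without torpor 1. Adipocyte markers lost the call at 0.101 after rescaling and 0.0741 without torpor 1. Hepatocyte markers and ribosomal protein genes were not called. Hepatocyte markers were called lower without summer active 2 (adjusted p = 1.50e-05) and after rescaling (0.0415), and higher without summer active 1 (0.00356). Ribosomal protein genes were called lower without summer active 1 (adjusted p = 0.0189) and higher without summer active 2 (0.00714). Of the genes fixed in advance, none passed. Differences that did not pass were -0.24 for the cold-inducible CIRBP, -0.55 for RBM3, 0.12 for the chaperone HSPA8, -0.25 for HSPA5, 1.17 for the early response gene FOS, -0.38 for EGR1 and -1.04 for PER1. The others were -0.99 for NR1D1 of the clock, -0.61 for the glucocorticoid target FKBP5, 0.87 for PDK4, -1.50 for the proliferation marker MKI67, 0.88 for S100A8, -5.27 for ALAS2 and 1.36 for the heme-degrading HMOX1, and the smallest limma adjusted p among these 14 was 0.112. The sign turned for CIRBP and HSPA5 to 0.15 and 0.14 after rescaling, for HSPA8 to -0.031 without summer active 1, for HSPA8 to -0.11 without torpor 2, and for S100A8 to -0.71 without torpor 1.

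**Figure D2:**
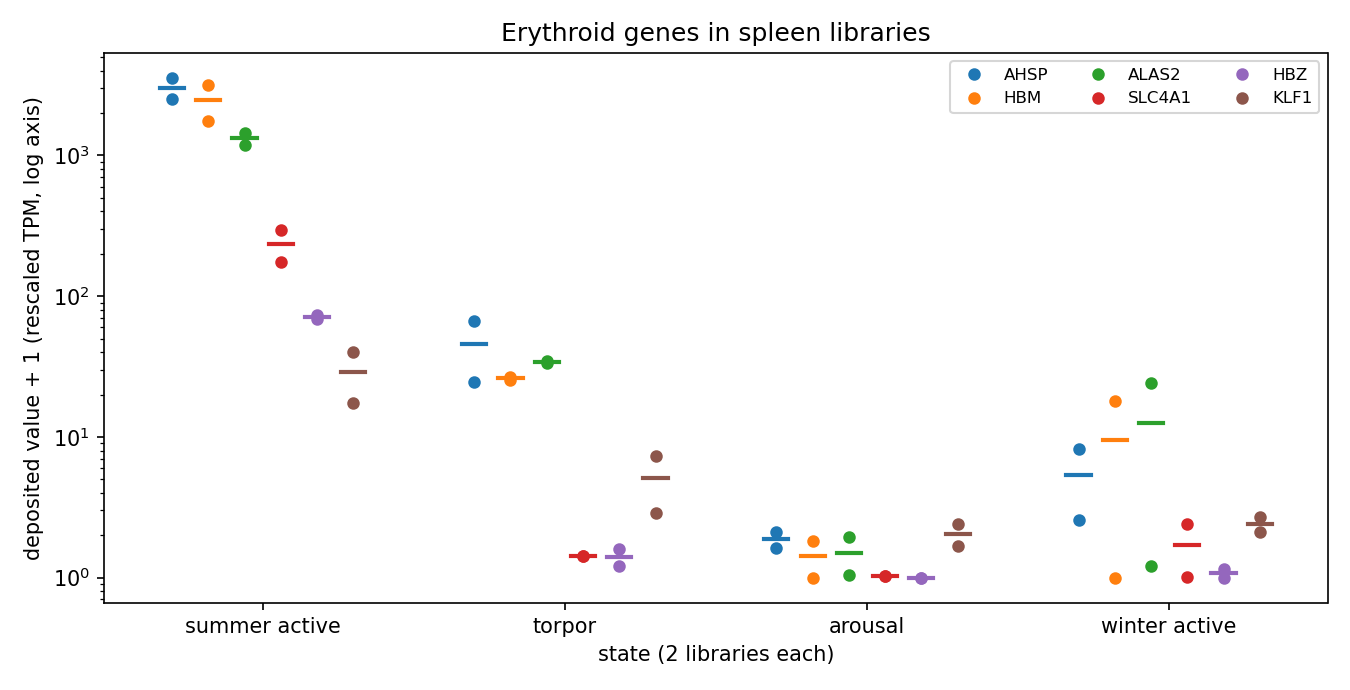
Deposited value + 1 (rescaled TPM, log axis) of 6 erythroid genes in the 4 states, with a point for each of the 2 libraries and a bar at their mean. The summer libraries lay above those of the 3 November states, as for AHSP at 2514 and 3548 in summer and at most 65.4 elsewhere.

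Arousal against torpor asks what differed 2 h after capture. Ribosomal protein and respiratory chain genes lay lower as groups, while no single gene passed. Genes with the smallest p on the higher side were the kinase HIPK3 (NCBI gene 117029966) at 63.4 ± 5.43 against 14.4 ± 1.44 and the ceramidase ACER2 at 18.6 ± 2.32 against 3.6 ± 0.747, with log2 differences of 2.07 (SE 0.23) and 2.10 (SE 0.25). FUT11, HYCC2, the metabolic regulator CREBRF and the Mediator subunit MED13L differed by 1.56, 1.74, 1.75 and 1.72. On the lower side stood AHSP (-4.44), TRAPPC2 (-1.29), VAMP5 (-1.09), TAF1D (-1.15), the cytotoxic granule gene GNLY (-1.80) and SELENOW (-0.93). Each of these 12 had an adjusted p of 0.142. No gene passed by limma: the smallest adjusted p was 0.142, while 2666 genes had an unadjusted p under 0.05 (1734 higher and 932 lower) and chance alone gives 677. The count was 2 without either winter active library. After rescaling, the all-gene median moved from 0.11 to 0.45 and 441 genes were higher and 4 lower.

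Ribosomal protein genes (75 of 76 members, median -0.69) and respiratory chain genes (52 of 55, median -0.47), which serve mitochondrial ATP synthesis, lay lower (adjusted p = 1.87e-25 and 2.59e-12). RPS21, RPL3 and RPS19 differed by -0.81, -0.75 and -0.92 and NDUFA2, NDUFC2 and NDUFS7 by -0.61, -0.69 and -0.67. Of ribosomal protein and respiratory chain genes, no member fell over all genes or adjusted over the list alone. Proteasome genes (28 of 33 members, median -0.28) lay lower (adjusted p = 4.57e-05). PSMD6, ADRM1 and PSMD8 differed by -0.58, -0.54 and -0.50, and no member fell over all genes or adjusted over the list alone. Mitosis genes (26 of 31 members, median -0.66) and S-phase genes (23 of 31, median -0.32) lay lower (adjusted p = 1.60e-07 and 0.00974). BIRC5, CCNB2 and UBE2C differed by -1.12, -1.22 and -1.32 and RFC4, TYMS and RFC3 by -0.70, -1.41 and -0.70. Of mitosis and S-phase genes, no member fell over all genes or adjusted over the list alone. Erythroid markers (19 of 23 members, median -0.45) lay lower (adjusted p = 4.57e-05). AHSP, ALAS2 and HBM differed by -4.44, -4.58 and -4.27, and none fell over all genes but 1 did adjusted over the list alone. None of the 16 lists called here passed with an estimated correlation (adjusted p = 0.85 to 0.937). The median was -0.13 for proteasome genes, -0.068 for S-phase genes and -0.28 for erythroid markers without torpor 1. The median was -0.29 for respiratory chain genes and -0.18 for proteasome genes without arousal 1, -0.36 for mitosis genes without arousal 2, and -0.47 and -0.052 for S-phase genes without arousal 1 and 2. Proteasome genes lost the call at 0.431 under quantile normalization, and S-phase genes at 0.153 without torpor 1 and 0.289 without arousal 2.

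NK cell markers (15 of 18 members, median -0.98) and platelet markers (15 of 18, median -0.99) lay lower (adjusted p = 7.55e-06 and 4.57e-05). GNLY, CCL5 and NKG7 differed by -1.80, -2.04 and -1.17 and GP1BB, GFI1B and PLEK by -1.39, -1.86 and -0.89. Of NK cell and platelet markers, none fell over all genes but 2 and 0 did adjusted over the list alone. Antigen presentation genes (17 of 19 members, median -0.51), which display peptides to T cells, and interferon-stimulated genes (23 of 37, median -0.26) lay lower (adjusted p = 4.57e-05 and 0.047). PSME1, PSME2 and B2M differed by -0.76, -0.67 and -1.05 and ZBP1, BST2 and IFI35 by -1.28, -1.04 and -0.56. Of antigen presentation and interferon-stimulated genes, no member fell over all genes or adjusted over the list alone. Neutrophil markers (19 of 20 members, median -0.92) and pancreatic markers (13 of 14, median -1.36) lay lower (adjusted p = 0.00162 and 0.00636). MPO and ELANE differed by -1.61 and -2.39 and CTRC, SYCN and CLPS by -2.11, -2.16 and -2.13. Of neutrophil and pancreatic markers, no member fell over all genes or adjusted over the list alone. The sign turned for CLPS to 0.029 without arousal 1. The median was -0.57 for NK cell markers without torpor 1, and -0.55 and -1.55 for platelet markers, 0.29 and -2.34 for neutrophil markers and -0.50 and -2.28 for pancreatic markers without torpor 1 and 2. The median was -0.18 for antigen presentation genes without arousal 2, and -0.46 and -0.080 for interferon-stimulated genes, -0.51 and -1.43 for neutrophil markers and 0.67 and -3.50 for pancreatic markers without arousal 1 and 2. Antigen presentation genes lost the call at 0.206 under quantile normalization, interferon-stimulated genes at 0.055 with a pseudocount of 0.1, 0.0649 under median-of-ratios rescaling, 0.0698 under quantile normalization, 0.257 without torpor 2 and 0.431 without arousal 2, and neutrophil markers at 0.722 without torpor 1 (direction turned). Pancreatic markers lost the call at 0.36 without torpor 1 and 0.623 without arousal 1 (direction turned).

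Glucocorticoid-induced genes (18 of 20 members, median 0.50) and circadian clock genes (15 of 19, median 0.68), which set daily rhythms, lay higher (adjusted p = 6.57e-04 and 0.0199). ZBTB16, FAM107A and PDK4 differed by 2.37, 1.11 and 1.37 and CLOCK, PER1 and RORA by 1.42, 1.01 and 0.98. Of glucocorticoid-induced and circadian clock genes, none rose over all genes but 7 and 4 did adjusted over the list alone. Endothelial markers (17 of 19 members, median 0.67) and hepatocyte markers (16 of 16, median 3.25) lay higher (adjusted p = 0.0231 and 0.00299). S1PR1, EMCN and ERG differed by 1.20, 0.91 and 0.96 and APOB, VTN and APOA1 by 2.98, 2.31 and 2.62. Of endothelial and hepatocyte markers, no member rose over all genes or adjusted over the list alone. The median was 1.00 for glucocorticoid-induced genes without torpor 1, and 0.43 for circadian clock genes and 2.07 for hepatocyte markers without torpor 2. The median was 0.87 for glucocorticoid-induced genes without arousal 1, and 5.25 and 1.68 for hepatocyte markers without arousal 1 and 2. Circadian clock genes lost the call at 0.0676 after rescaling, 0.307 without torpor 2 and 0.218 without arousal 2, endothelial markers at 0.077 after rescaling, 0.0879 without torpor 2 and 0.0845 without arousal 2, and hepatocyte markers at 0.13 after rescaling, 0.257 without torpor 2 and 0.344 without arousal 2.

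Among the genes fixed in advance, none passed. Differences that did not pass were -0.40 for CIRBP, -0.33 for RBM3, 0.14 for HSPA8, 0.51 for HSPA5, -0.21 for FOS, 0.64 for EGR1 and 1.01 for PER1. The others were -0.69 for NR1D1, 1.02 for FKBP5, 1.37 for PDK4, -0.35 for MKI67, -1.28 for S100A8, -4.58 for ALAS2 and -0.21 for HMOX1, and the smallest limma adjusted p among these 14 was 0.143. The sign turned for RBM3, FOS and HMOX1 to 0.047, 0.11 and 0.17 after rescaling, for HSPA8 and S100A8 to -0.092 and 0.30 without torpor 1, for HSPA8 to -0.18 without arousal 1, for FOS, MKI67 and HMOX1 to 0.063, 0.39 and 0.59 without arousal 2, for HMOX1 to 0.38 under quantile normalization, and for HMOX1 to 0.071 without torpor 2.

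Winter active against torpor asks how bats 26 h after capture differed from torpid bats. Mitosis genes lay lower and glucocorticoid-induced genes higher as groups, while no single gene passed. On the higher side, HIPK3 stood at 49.8 ± 12.9 against 14.4 ± 1.44 (log2 difference 1.71, SE 0.23) and the Notch target HES1 at 49.7 ± 12.4 against 12 ± 3.97 (log2 difference 1.98, SE 0.31). ENC1, the dystrophin relative UTRN, CCDC126 and the pro-apoptotic BMF differed by 1.52, 1.48, 1.35 and 1.35. On the lower side stood TAF1D (-1.60), H1-4 (-3.05), GNLY (-2.41), ATP5MK (-1.12), SKA3 (-1.12) and AHSP (-3.13). Adjusted p-values of these 12 lay between 0.22 and 0.271. No gene passed by limma: the smallest adjusted p was 0.22, while 1787 genes had an unadjusted p under 0.05, 1231 higher and 556 lower. The count was 4 with no filter. Rescaling to 1000000 moved the all-gene median from 0.079 to 0.24 and left no gene past the threshold.

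Glucocorticoid-induced genes (17 of 20 members, median 0.57) and B-cell markers (20 of 21, median 0.55) lay higher (adjusted p = 8.18e-04 and 0.00365). FAM107A, KLF9 and ZBTB16 differed by 1.34, 2.06 and 2.13 and VPREB3, CXCR5 and MS4A1 by 1.03, 2.35 and 1.35. Of glucocorticoid-induced genes and B-cell markers, none rose over all genes but 5 and 2 did adjusted over the list alone. Endothelial markers (17 of 19 members, median 0.66) and immediate early genes (24 of 29, median 0.44), which respond first to many stimuli, lay higher (adjusted p = 0.00141 and 0.0127). EMCN, LYVE1 and S1PR1 differed by 1.41, 1.42 and 1.19 and BTG2, MYC and DUSP1 by 2.30, 0.85 and 1.10. Of endothelial markers and immediate early genes, none rose over all genes but 3 and 2 did adjusted over the list alone. Dendritic cell markers (14 of 15 members, median 0.48) and interferon-stimulated genes (26 of 37, median 0.44) lay higher (adjusted p = 0.0127 and 0.0337). IRF8, TCF4 and XCR1 differed by 1.09, 1.03 and 0.98 and IFIT1, OAS3 and IFIT5 by 1.56, 0.98 and 0.84. Of dendritic cell markers and interferon-stimulated genes, none rose over all genes but 2 and 0 did adjusted over the list alone. None of the 17 lists called here passed with an estimated correlation (adjusted p = 0.764 to 0.842). The median was 0.28 for interferon-stimulated genes without torpor 1. The median was 0.13 and 0.75 for dendritic cell markers and -0.12 and 0.77 for interferon-stimulated genes without winter active 1 and 2. B-cell markers lost the call at 0.188 without winter active 1, immediate early genes at 0.162 without torpor 2 and 0.0559 without winter active 1, and dendritic cell markers at 0.10 without torpor 2 and 0.376 without winter active 1. Interferon-stimulated genes lost the call at 0.0512 with a pseudocount of 0.1, 0.134 without torpor 1, 0.0542 without arousal 1, 0.0549 without arousal 2 and 0.39 without winter active 1 (direction turned).

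Mitosis genes (29 of 31 members, median -0.65) and S-phase genes (23 of 31, median -0.27) lay lower (adjusted p = 1.92e-08 and 0.0146). CCNB2, BIRC5 and TPX2 differed by -0.96, -0.82 and -0.82 and RFC3, E2F1 and CCNE1 by -0.60, -0.84 and -0.46. Of mitosis and S-phase genes, no member fell over all genes or adjusted over the list alone. Ribosomal protein genes (70 of 76 members, median -0.20, turned under quantile normalization at adjusted p = 0.919) and respiratory chain genes (47 of 55, median -0.21) lay lower (adjusted p = 6.92e-06 and 1.11e-06). RPL9, RPS20 and RPL31 differed by -0.93, -0.61 and -0.59 and NDUFB4, ATP5MC3 and NDUFB6 by -0.68, -0.46 and -0.57. Of ribosomal protein and respiratory chain genes, no member fell over all genes or adjusted over the list alone. Proteasome genes (29 of 33 members, median -0.28) and NRF2 targets (20 of 30, median -0.19), which counter oxidants, lay lower (adjusted p = 1.86e-06 and 0.0238). PSMD6, PSMD14 and ADRM1 differed by -0.63, -0.56 and -0.59 and TXN, GPX4 and FTH1 by -0.67, -0.52 and -0.83. Of proteasome genes and NRF2 targets, no member fell over all genes or adjusted over the list alone. Antigen presentation genes (14 of 19 members, median -0.20) lay lower (adjusted p = 0.0337). CTSH, PSMB10 and PDIA3 differed by -0.87, -0.54 and -0.32, and no member fell over all genes or adjusted over the list alone. The median was -0.11 for S-phase genes, -0.13 for proteasome genes and -0.13 for antigen presentation genes without torpor 1. The median was -0.18 for S-phase genes without winter active 2, and -0.35 and -0.030 for ribosomal protein genes and -0.38 and -0.030 for antigen presentation genes without winter active 1 and 2. S-phase genes lost the call at 0.256 without torpor 1 and 0.0619 without winter active 2, ribosomal protein genes at 0.11 without winter active 2, and respiratory chain genes at 0.176 under quantile normalization. Proteasome genes lost the call at 0.0807 under quantile normalization, NRF2 targets at 0.54 under quantile normalization, 0.105 without torpor 1 and 0.0559 without winter active 1, and antigen presentation genes at 0.919 under quantile normalization, 0.0683 after rescaling, 0.0756 without torpor 1, 0.0728 without torpor 2 and 0.484 without winter active 2.

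Erythroid markers (17 of 23 members, median -0.26) lay lower (adjusted p = 0.00158). AHSP, ALAS2 and HBM differed by -3.13, -2.66 and -2.62, and none fell over all genes but 1 did adjusted over the list alone. Neutrophil markers (18 of 20 members, median -1.31) lay lower (adjusted p = 3.79e-04). MMP9, CEBPE and S100A9 differed by -1.71, -1.25 and -2.01, and no member fell over all genes or adjusted over the list alone. Pancreatic markers (14 of 14 members, median -2.59) and hepatocyte markers (16 of 16, median -2.26) lay lower (adjusted p = 1.10e-07 and 0.00101). CTRC, SYCN and CTRL differed by -4.13, -4.01 and -2.44 and APOA2, HPX and AMBP by -3.25, -3.79 and -3.09. Of pancreatic and hepatocyte markers, no member fell over all genes or adjusted over the list alone. The median was -0.043 and -0.58 for erythroid markers, 0.11 and -2.56 for neutrophil markers and -0.72 and -3.87 for hepatocyte markers without torpor 1 and 2. Erythroid markers lost the call at 0.105 without torpor 1 and 0.0548 without winter active 2, neutrophil markers at 0.814 without torpor 1 (direction turned), and hepatocyte markers at 0.161 without torpor 1. The genes fixed in advance did not pass either. Differences that did not pass were -0.37 for CIRBP, -0.048 for RBM3, 0.28 for HSPA8, 0.58 for HSPA5, -0.59 for FOS, 0.87 for EGR1 and 1.07 for PER1. The others were -0.30 for NR1D1, 0.78 for FKBP5, 0.57 for PDK4, -0.52 for MKI67, -1.80 for S100A8, -2.66 for ALAS2 and -0.51 for HMOX1, and the smallest limma adjusted p among these 14 was 0.274. The sign turned for RBM3 to 0.089 under quantile normalization, for RBM3 to 0.13 after rescaling, and for RBM3 to 0.0062 without torpor 1.

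Winter active against summer active compares active bats across the seasons. Erythroid genes had the largest falls among the genes named by the rule. AHSP stood at 4.39 ± 3.99 against 3031 ± 731 (log2 difference -9.35, SE 0.62, adjusted p = 0.00236), and HBM, ALAS2, SLC4A1, HBZ and HEMGN fell, with differences of -9.12, -7.92, -7.20, -6.05 and -5.57 (adjusted p = 0.0192, 0.0336, 0.00236, 7.86e-04 and 0.00257). The mitosis genes BIRC5, AURKB and DLGAP5 fell, to 32.3 ± 7.36 against 208 ± 80.4, 5.69 ± 0.236 against 35.9 ± 8.45 and 4.13 ± 0.212 against 33.4 ± 16.3. The metalloreductase STEAP2 (NCBI gene 117012462) and STEAP1 rose, at 24.2 ± 2.95 against 5.31 ± 2.69 and 35.6 ± 14 against 7.48 ± 0.295 (adjusted p = 0.0401 and 0.0403). RHOJ, GPR55, PHACTR2 and the antiviral kinase EIF2AK2 rose by 1.94, 1.82, 1.72 and 1.60 (adjusted p = 0.0468, 0.0342, 0.0203 and 0.0447). In all, 140 genes changed, 19 higher and 121 lower. Higher and lower genes numbered 93 and 289 without summer active 1, 1 and 30 without summer active 2, 4 and 61 without either torpor library, 1 and 69 without arousal 1, 1 and 71 without arousal 2, 12 and 34 without winter active 1, 0 and 15 without winter active 2, and 6 and 88 with no filter. The 4 libraries alone gave 32. The all-gene median moved from 0.046 to 0.55 after rescaling, and 662 genes were then higher and 117 lower. Of the 17 named genes that passed, the call was lost by 9 with no filter (adjusted p = 0.0543 to 0.103), 12 in a fit of the 2 states alone (0.0667 to 0.192), 3 with a pseudocount of 0.1 (0.0659 to 0.0815), 1 under quantile normalization (0.0507), 2 under robust eBayes (0.050 to 0.0771) and 8 without arousal 1 (0.0551 to 0.0908). It was lost by 8 without arousal 2 (0.0536 to 0.0904), 3 without summer active 1 (0.0557 to 0.0743), 12 without summer active 2 (0.0611 to 0.237), 9 without torpor 1 (0.0537 to 0.094), 9 without torpor 2 (0.0532 to 0.0933), 10 without winter active 1 (0.0534 to 0.185) and 11 without winter active 2 (0.127 to 0.372). AHSP, SLC4A1, HBZ and HEMGN kept the call in all 8 fits without a library.

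Erythroid markers (23 of 23 members, median -3.48) lay lower (adjusted p = 2.49e-35). HBZ, SLC4A1 and AHSP differed by -6.05, -7.20 and -9.35, and all passed, and 18 fell over all genes and 21 adjusted over the list alone. Mitosis genes (30 of 31 members, median -1.99) and S-phase genes (30 of 31, median -0.96) lay lower (adjusted p = 8.55e-31 and 1.02e-13). BIRC5, AURKB and DLGAP5 differed by -2.61, -2.45 and -2.66 and RRM2, E2F1 and CDT1 by -2.53, -2.13 and -1.86, of which BIRC5, AURKB and DLGAP5 passed (limma adjusted p = 0.0131, 0.0172 and 0.0217). Of mitosis and S-phase genes, 14 and 0 fell over all genes and 29 and 19 adjusted over the list alone. B-cell markers (16 of 21 members, median -0.73) and T-cell markers (16 of 23, median -0.34) lay lower (adjusted p = 5.11e-05 and 0.0152). VPREB3, CD79B and FCRLA differed by -1.94, -1.83 and -1.56 and CD5, SIT1 and UBASH3A by -0.82, -0.76 and -0.73, of which VPREB3 and CD79B passed (limma adjusted p = 0.00887 and 0.0412). Of B-cell and T-cell markers, 2 and 0 fell over all genes and 7 and 0 adjusted over the list alone. None of the 19 lists called here passed with an estimated correlation (adjusted p = 0.515 to 0.723). For erythroid markers fry gave an adjusted p = 0.00874. The median was -0.55 for S-phase genes without summer active 2, and -1.18 and -0.33 for B-cell markers without summer active 1 and 2. The median was -0.12 for T-cell markers without winter active 2. T-cell markers lost the call at 0.207 without summer active 2 and 0.602 without winter active 2.

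Ribosomal protein genes (68 of 76 members, median -0.28) and respiratory chain genes (49 of 55, median -0.21) lay lower (adjusted p = 4.92e-05 and 5.07e-04). RPS27A and FAU differed by -0.58 and -0.60 and ATP5MC3, NDUFA2 and NDUFA13 by -0.47, -0.42 and -0.62. Of ribosomal protein and respiratory chain genes, no member fell over all genes or adjusted over the list alone. Proteasome genes (26 of 33 members, median -0.18, turned after rescaling at adjusted p = 0.752) and cold-inducible RNA-binding proteins (5 of 5, median -0.60) lay lower (adjusted p = 0.0214 and 0.0108). ADRM1, PSMD4 and PSMD13 differed by -0.43, -0.43 and -0.38 and CIRBP, SRSF5 and SRSF2 by -0.61, -1.02 and -0.45. Of proteasome genes and cold-inducible RNA-binding proteins, no member fell over all genes or adjusted over the list alone. Hepatocyte markers (16 of 16 members, median -2.81) lay lower (adjusted p = 7.37e-04). VTN, APOA2 and FGB differed by -2.12, -3.10 and -3.50, and no member fell over all genes or adjusted over the list alone. The sign turned for ATP5MC3, NDUFA2, ADRM1, PSMD4, PSMD13 and SRSF2 to 0.10, 0.15, 0.14, 0.13, 0.19 and 0.11 after rescaling. The median was -0.096 for proteasome genes and -0.35 for cold-inducible RNA-binding proteins without summer active 2, and -0.51 and -0.061 for ribosomal protein genes and -0.016 and -5.58 for hepatocyte markers without summer active 1 and 2. The median was -0.43 and -0.12 for ribosomal protein genes without winter active 1 and 2. Ribosomal protein genes lost the call at 0.94 under quantile normalization, 0.284 after rescaling, 0.333 without summer active 2 and 0.113 without winter active 2, respiratory chain genes at 0.138 under quantile normalization and 0.797 after rescaling, and proteasome genes at 0.582 under quantile normalization, 0.0875 without summer active 1, 0.0709 without summer active 2 and 0.12 without winter active 1. Cold-inducible RNA-binding proteins lost the call at 0.067 after rescaling and 0.0924 without summer active 2, and hepatocyte markers at 0.943 without summer active 1.

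Interferon-stimulated genes (34 of 37 members, median 0.98) and pattern recognition receptors (24 of 30, median 0.49) lay higher (adjusted p = 2.09e-09 and 6.37e-04). EIF2AK2, RIGI and PARP14 differed by 1.60, 1.33 and 1.57 and RIGI, STING1 and TLR6 by 1.33, 1.28 and 0.98, of which EIF2AK2 passed. Of interferon-stimulated genes and pattern recognition receptors, 1 and 0 rose over all genes and 6 and 4 adjusted over the list alone. NF-kB and cytokine genes (20 of 25 members, median 0.83), which drive inflammation, and immediate early genes (22 of 29, median 0.46) lay higher (adjusted p = 0.00186 and 0.0088). TNFSF10, TNF and NFKBIZ differed by 1.44, 1.97 and 1.34 and MYC, JUN and ATF3 by 0.78, 1.37 and 1.98. Of NF-kB and cytokine and immediate early genes, none rose over all genes but 0 and 6 did adjusted over the list alone. Macrophage markers (20 of 24 members, median 0.64) lay higher (adjusted p = 0.0135). VCAM1, TIMD4 and MARCO differed by 1.12, 1.3 and 1.39, and no member rose over all genes or adjusted over the list alone. The median was 0.64 for interferon-stimulated genes and 0.24 for pattern recognition receptors without summer active 2, and 1.38 and -0.11 for macrophage markers without summer active 1 and 2. The median was 0.54 for interferon-stimulated genes and 0.29 for immediate early genes without winter active 1. Pattern recognition receptors lost the call at 0.0907 without summer active 2, NF-kB and cytokine genes at 0.067 after rescaling, and immediate early genes at 0.103 after rescaling. Macrophage markers lost the call at 0.246 after rescaling, 0.493 without summer active 2 (direction turned) and 0.309 without winter active 1.

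Unfolded protein response genes (18 of 22 members, median 0.27) and plasma cell markers (12 of 13, median 0.58) lay higher (adjusted p = 0.0152 and 0.0152). SEL1L, ERN1 and HSP90B1 differed by 1.64, 0.91 and 0.74 and FKBP11, JCHAIN and MZB1 by 0.91, 1.24 and 0.92. Of unfolded protein response genes and plasma cell markers, none rose over all genes but 1 and 0 did adjusted over the list alone. Endothelial markers (17 of 19 members, median 0.40) and adipocyte markers (12 of 14, median 0.92) lay higher (adjusted p = 0.0244 and 0.00366). EMCN, KDR and PECAM1 differed by 1.33, 1.13 and 0.75 and PLIN1, ADIPOQ and CIDEA by 3.46, 4.34 and 3.10. Of endothelial and adipocyte markers, none rose over all genes but 1 and 3 did adjusted over the list alone. The median was 1.09 and -0.093 for endothelial markers without summer active 1 and 2. The median was 1.47 for adipocyte markers without winter active 1. Unfolded protein response genes lost the call at 0.0839 without summer active 1 and 0.132 without winter active 1, plasma cell markers at 0.0601 after rescaling, 0.347 without summer active 1 and 0.149 without winter active 1, and endothelial markers at 0.258 after rescaling, 0.533 without summer active 2 (direction turned) and 0.132 without winter active 1. Adipocyte markers lost the call at 0.291 after rescaling. Of the genes fixed in advance, ALAS2 passed. Differences that did not pass were -0.61 for CIRBP, -0.60 for RBM3, 0.41 for HSPA8, 0.33 for HSPA5, 0.58 for FOS and 0.49 for EGR1. The others were 0.031 for PER1, -1.29 for NR1D1, 0.16 for FKBP5, 1.44 for PDK4, -2.02 for MKI67, -0.92 for S100A8 and 0.86 for HMOX1, and the smallest limma adjusted p among these 13 was 0.0826. The sign turned for EGR1 to -0.043 without winter active 2, for PER1 to -0.012 under median-of-ratios rescaling, for PER1 to -0.031 under quantile normalization, for PER1 to -0.29 without winter active 1, and for FKBP5 and HMOX1 to -0.20 and -0.065 without summer active 2.

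A secondary comparison, arousal against summer active, had the most changed genes of the 6 with all 8 libraries. HBM, AHSP and ALAS2 fell, at 0.415 ± 0.586 against 2458 ± 980.1, 0.865 ± 0.328 against 3031 ± 731 and 0.492 ± 0.636 against 1318 ± 188 (adjusted p = 0.00852, 0.00129 and 0.0105). The lipid droplet gene PLIN1 rose, at 12.5 ± 8.86 against 0.183 ± 0.176 (adjusted p = 0.0442), and FNIP2 at 41.5 ± 13.3 against 6.36 ± 4.53 (adjusted p = 0.0321). CLPSL2 was at 5.58 ± 1.91 in arousal and listed at 0 in both summer libraries (adjusted p = 0.0158). In all, 748 genes changed, 323 higher and 425 lower. Higher and lower genes numbered 222 and 466 without summer active 1, 4 and 46 without summer active 2, 108 and 198 without torpor 1, 102 and 192 without torpor 2, 4 and 37 without arousal 1, 1 and 25 without arousal 2, 47 and 144 without winter active 1, 46 and 143 without winter active 2, and 70 and 214 with no filter. The 4 libraries alone gave 27. The all-gene median moved from 0.083 to 0.76 after rescaling, and 5833 genes were then higher and 266 lower. Of the 6 named genes that passed, the call was lost by 2 with no filter (adjusted p = 0.0601 to 0.0785), 3 in a fit of the 2 states alone (0.0851 to 0.12), 5 without arousal 1 (0.0648 to 0.138), 5 without arousal 2 (0.0566 to 0.125) and 1 without summer active 1 (0.0817). It was lost by 5 without summer active 2 (0.0562 to 0.146), 1 without torpor 1 (0.0706), 2 without torpor 2 (0.0505 to 0.071), 1 without winter active 1 (0.0639) and 1 without winter active 2 (0.0635). AHSP kept the call in all 8 fits without a library.

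Erythroid markers (23 of 23 members, median -3.72) lay lower (adjusted p = 7.76e-25), and 21 fell over all genes and 22 adjusted over the list alone. Mitosis genes (30 of 31 members, median -1.95) and S-phase genes (28 of 31, median -1.04) lay lower (adjusted p = 8.15e-21 and 1.11e-09), and 22 and 10 fell over all genes and 29 and 18 adjusted over the list alone. B-cell markers (19 of 21 members, median -1.29) and T-cell markers (20 of 23, median -0.85) lay lower (adjusted p = 7.20e-07 and 7.60e-06), and 7 and 2 fell over all genes and 10 and 11 adjusted over the list alone. NK cell markers (16 of 18 members, median -0.77) and antigen presentation genes (13 of 19, median -0.36) lay lower (adjusted p = 2.01e-04 and 0.0436), and 2 and 1 fell over all genes and 5 and 3 adjusted over the list alone. None of the 15 lists called here passed with an estimated correlation (adjusted p = 0.834). For erythroid markers fry gave an adjusted p = 0.00739. The median was -0.68 for S-phase genes without summer active 2. The median was 0.045 for antigen presentation genes without arousal 2. Antigen presentation genes lost the call at 0.757 under quantile normalization, 0.376 after rescaling, 0.162 without summer active 1 and 0.562 without arousal 2.

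Ribosomal protein genes (72 of 76 members, median -0.79) and respiratory chain genes (49 of 55, median -0.40) lay lower (adjusted p = 1.61e-16 and 8.19e-07), and 3 and 2 fell over all genes and 47 and 2 adjusted over the list alone. Cold-inducible RNA-binding proteins (5 of 5 members, median -0.64) lay lower (adjusted p = 0.0379), and none fell over all genes but 3 did adjusted over the list alone. Chaperones (21 of 25 members, median 0.34) and pattern recognition receptors (23 of 30, median 0.50) lay higher (adjusted p = 0.0332 and 0.0332), and 1 and 1 rose over all genes and 1 and 6 adjusted over the list alone. Pancreatic markers (14 of 14 members, median 2.64), adipocyte markers (12 of 14, median 1.42) and hepatocyte markers (16 of 16, median 2.89, turned after rescaling at adjusted p = 0.932) lay higher (adjusted p = 0.00371, 0.0133 and 0.0332), and 0, 1 and 0 rose over all genes and 0, 3 and 0 adjusted over the list alone. The median was 0.20 for pattern recognition receptors without summer active 2, and 5.76 and 0.42 for hepatocyte markers without summer active 1 and 2. The median was -0.24 for respiratory chain genes and 0.30 for pattern recognition receptors without arousal 1, and 4.79 and 0.61 for pancreatic markers, 2.64 and 0.58 for adipocyte markers and 4.64 and 1.00 for hepatocyte markers without arousal 1 and 2. Respiratory chain genes lost the call at 0.269 after rescaling, cold-inducible RNA-binding proteins at 0.125 under quantile normalization, 0.218 after rescaling, 0.169 without summer active 2 and 0.0879 without arousal 1, and chaperones at 0.243 without summer active 1 and 0.202 without arousal 1. Pattern recognition receptors lost the call at 0.0899 under quantile normalization, 0.125 after rescaling, 0.323 without summer active 2 and 0.309 without arousal 1, pancreatic markers at 0.565 after rescaling and 0.362 without arousal 2, and adipocyte markers at 0.387 after rescaling, 0.0602 without summer active 2 and 0.0536 without arousal 2. Hepatocyte markers lost the call at 0.891 without summer active 2 (direction turned) and 0.601 without arousal 2.

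Calls of the 3 comparisons with summer overlapped. In all 3 November states, 56 genes were lower and 4 higher. With replicate 1 and then 2 of a state left out, the lower genes were 200 and 21 for summer active, 27 and 8 for torpor, 27 and 24 for arousal and 26 and 14 for winter active, and the higher genes 23, 0, 1, 0, 1, 0, 0 and 0 in the same order. These fits held 8 to 51 of the 56 and 0 to 2 of the 4. There were 35 lower and 12 higher after rescaling, and 53 and 0 with no filter. Independent lists would share 0.0185 and 3.35e-04, and 50 simulations of unchanged groups against the same summer libraries shared 0 on average. Such groups gave 0.207 calls per comparison, so this sets no level for lists of this size. Part of the overlap may come from the 2 shared summer libraries, too few to split.

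**Figure D3:**
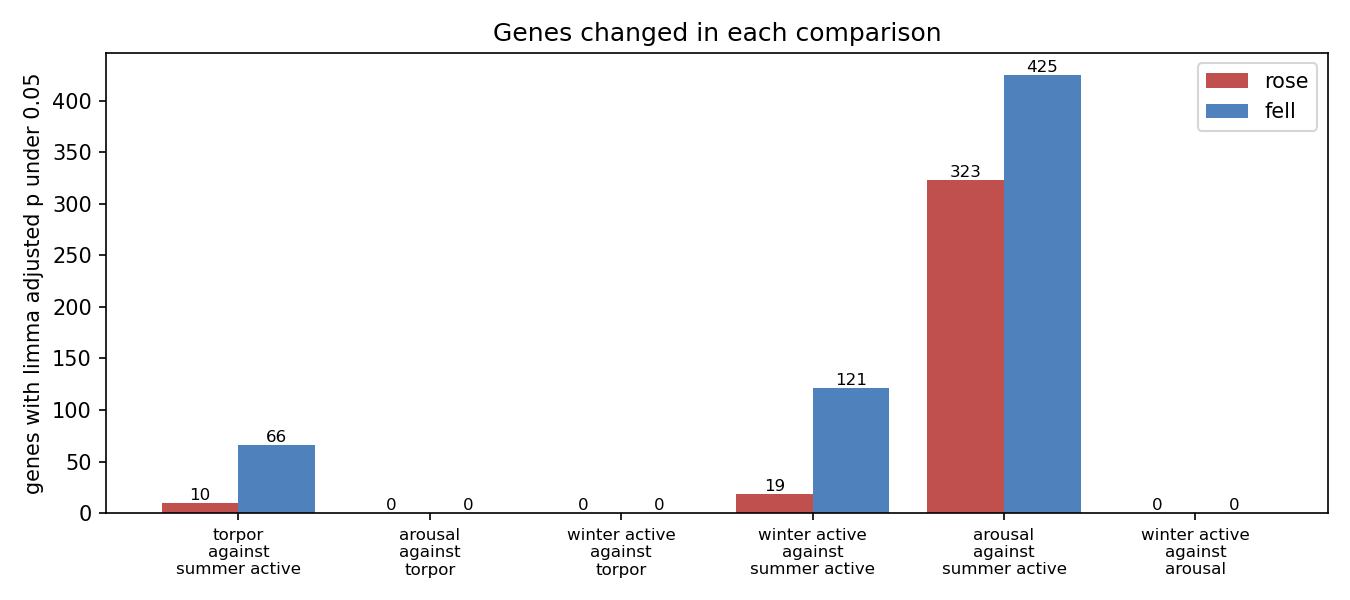
Bars give the number of genes past a limma adjusted p of 0.05 in each of the 6 comparisons, higher and lower apart, from 0 on a linear axis. Falls outnumbered rises in each comparison with summer and the 3 comparisons within November had 0 genes, while after rescaling to 1000000 rises outnumbered falls for arousal and winter active against summer and arousal against torpor had 445 genes.

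Winter active against arousal, also secondary, sets 26 h against 2 h after capture. No gene passed by limma, and the smallest adjusted p was 0.227. Unadjusted, 738 genes had a p under 0.05, close to the 677 that chance alone gives. The interferon-induced IFI27, LYZL4 and BANF1 had the smallest p on the higher side and differed by 1.64, 1.67 and 1.00. SEC61A2, CHCHD10 and H1-4 differed by -1.04, -1.06 and -1.85 on the lower side. The count was 1 with no filter and 1 without winter active 2. Rescaling to 1000000 moved the all-gene median from -0.037 to -0.22 and left no gene past the threshold.

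Ribosomal protein genes (73 of 76 members, median 0.53) and respiratory chain genes (40 of 55, median 0.21) lay higher (adjusted p = 2.87e-21 and 1.86e-04), and no member rose over all genes or adjusted over the list alone. Interferon-stimulated genes (32 of 37 members, median 0.54) and antigen presentation genes (15 of 19, median 0.28) lay higher (adjusted p = 4.51e-09 and 0.0014), and no member rose over all genes or adjusted over the list alone. B-cell markers (21 of 21 members, median 0.44), T-cell markers (22 of 23, median 0.51) and NK cell markers (16 of 18, median 0.58) lay higher (adjusted p = 1.14e-05, 9.09e-07 and 2.68e-05), and no member rose over all genes or adjusted over the list alone. None of the 15 lists called here passed with an estimated correlation (adjusted p = 0.817 to 0.954). The median was 0.34 for ribosomal protein genes and 0.50 for antigen presentation genes without arousal 1, and 0.044 and 0.33 for respiratory chain genes, 0.77 and 0.17 for B-cell markers and 0.84 and 0.26 for T-cell markers without arousal 1 and 2. The median was 0.13 for respiratory chain genes without winter active 1, and 0.25 and 0.85 for interferon-stimulated genes, 0.086 and 0.53 for antigen presentation genes and 0.19 and 0.77 for T-cell markers without winter active 1 and 2. Respiratory chain genes lost the call at 0.564 without arousal 1, interferon-stimulated genes at 0.0587 without winter active 1, and antigen presentation genes at 0.104 under quantile normalization, 0.471 without arousal 2 and 0.173 without winter active 1. B-cell markers lost the call at 0.17 without arousal 2, and T-cell markers at 0.132 without arousal 2.

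Plasma cell markers (9 of 13 members, median 0.13) and dendritic cell markers (13 of 15, median 0.38) lay higher (adjusted p = 0.0209 and 0.0287), and none rose over all genes but 1 and 0 did adjusted over the list alone. Platelet markers (15 of 18 members, median 0.77) and erythroid markers (19 of 23, median 0.24) lay higher (adjusted p = 1.14e-05 and 0.0355), and no member rose over all genes or adjusted over the list alone. Hepatocyte markers (16 of 16 members, median -5.83) and pancreatic markers (14 of 14, median -1.31) lay lower (adjusted p = 8.90e-14 and 0.0024), and none fell over all genes but 15 and 0 did adjusted over the list alone. Fatty acid oxidation genes (22 of 29 members, median -0.30) and ribosome biogenesis genes (21 of 31, median -0.21) lay lower (adjusted p = 0.0126 and 0.0355), and no member fell over all genes or adjusted over the list alone. The median was -0.12 for ribosome biogenesis genes without arousal 1, -3.85 for hepatocyte markers and -0.18 for fatty acid oxidation genes without arousal 2, and 0.39 and -0.082 for plasma cell markers and -3.40 and 0.33 for pancreatic markers without arousal 1 and 2. The median was -0.050 for dendritic cell markers without winter active 1, 0.30 for plasma cell markers without winter active 2, and 0 and 0.40 for erythroid markers and -0.70 and -2.17 for pancreatic markers without winter active 1 and 2. Plasma cell markers lost the call at 0.451 without arousal 2 and 0.146 without winter active 1, dendritic cell markers at 0.293 without arousal 2 and 0.747 without winter active 1, and erythroid markers at 0.0568 under median-of-ratios rescaling, 0.281 without arousal 1, 0.0523 without arousal 2 and 0.852 without winter active 1. Pancreatic markers lost the call at 0.0742 after rescaling, 0.294 without arousal 2 (direction turned) and 0.221 without winter active 1, fatty acid oxidation genes at 0.37 without arousal 2 and 0.0763 without winter active 1, and ribosome biogenesis genes at 0.289 without arousal 1, 0.0829 without winter active 1 and 0.109 without winter active 2.

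Across all 4 states, the limma F test called 106 genes. No gene passed by limma in one direction against both torpor and winter active in arousal, the criterion for a transient gene, and 275 genes met it at an unadjusted p under 0.05. The F test count was 16 without summer active 2 and 190 without summer active 1. With replicate 1 or 2 left out, it was 34 or 31 for torpor, 37 or 30 for arousal and 32 or 28 for winter active. It was 40 with no filter and 2977 after rescaling, and without winter active 2 the transient count was 1.

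**Figure D4:**
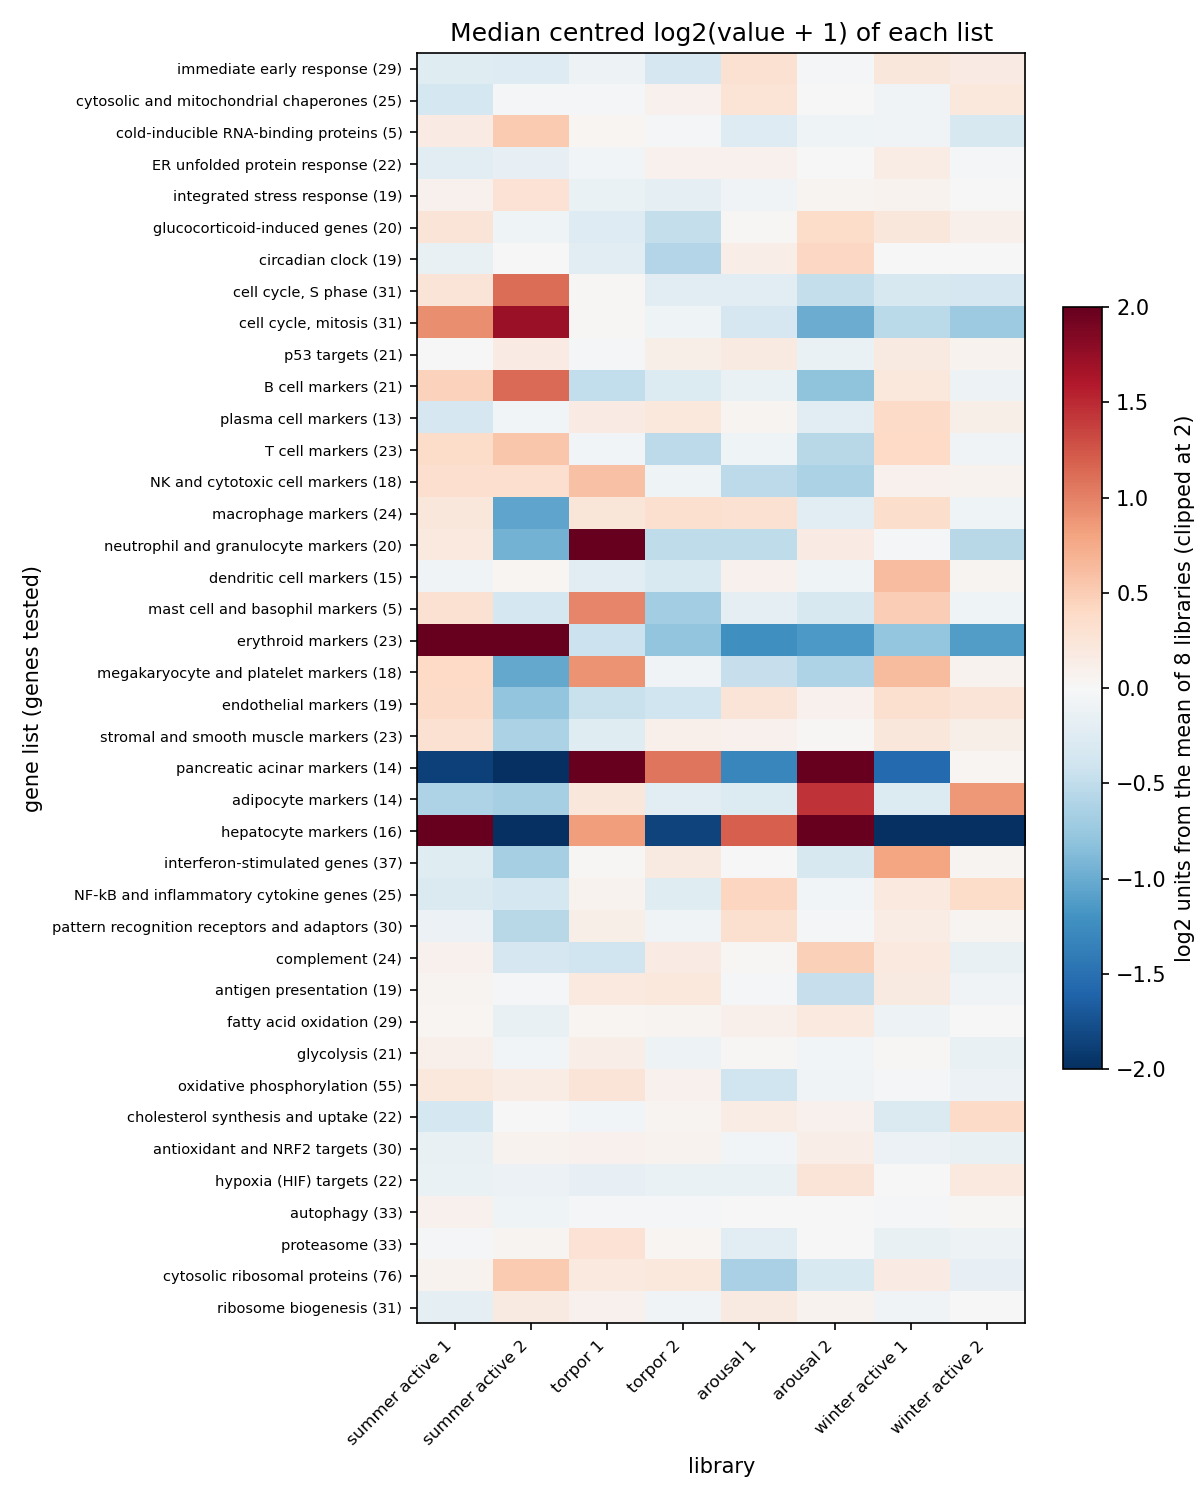
Colour gives the median centred log2(value + 1) of each of 40 gene lists (down the side, with genes tested) in the 8 libraries (across), from the 8-library mean and clipped at 2. Erythroid markers stood at 2.29 and 3.03 in the summer libraries, and hepatocyte markers ranged from -2.80 to 4.70.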

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

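The tests in this part, except the one on gene span, were chosen after the result was seen. In 5 gene lists, picked by their camera call in winter active against arousal, the median log2 difference from torpor had opposite signs at 2 h (arousal) and 26 h (winter active) after capture. Medians were 3.25 and -2.26 for hepatocyte markers (camera adjusted p = 8.90e-14) and -0.26 and 0.44 for interferon-stimulated genes (4.51e-09). They were 0.096 and -0.029 for fatty acid oxidation genes (0.0126) and -0.020 and 0.29 for plasma cell markers (0.0209). Ribosome biogenesis genes had 0.15 and -0.0023 (0.0355). With an estimated correlation, these adjusted p-values were 0.817, 0.817, 0.817, 0.84 and 0.954. Interferon-stimulated genes lost the call at adjusted p = 0.0587 without winter active 1, and fatty acid oxidation genes at 0.37 without arousal 2 and 0.0763 without winter active 1. Plasma cell markers lost the call at adjusted p = 0.451 without arousal 2 and 0.146 without winter active 1, and ribosome biogenesis genes at 0.289 without arousal 1, 0.0829 without winter active 1 and 0.109 without winter active 2. Against torpor, camera called the last 3 lists at neither time, and the calls of the first 2 were lost with an estimated correlation (adjusted p = 0.764 to 0.937). Hepatocyte markers lost the call at 2 h against torpor at adjusted p = 0.257 without torpor 2 and 0.344 without arousal 2, and interferon-stimulated genes at 0.257 without torpor 2 and 0.431 without arousal 2. The median was 2.07 for hepatocyte markers without torpor 2. The median was 5.25 and 1.68 for hepatocyte markers and -0.46 and -0.080 for interferon-stimulated genes without arousal 1 and 2. Hepatocyte markers lost the call at 26 h against torpor at adjusted p = 0.161 without torpor 1, and interferon-stimulated genes at 0.134 without torpor 1, 0.0542 without arousal 1, 0.0549 without arousal 2 and 0.39 without winter active 1 (direction turned). The median was 0.28 for interferon-stimulated genes without torpor 1, and -0.72 and -3.87 for hepatocyte markers without torpor 1 and 2. The median was -0.12 and 0.77 for interferon-stimulated genes without winter active 1 and 2. The side of torpor is uncertain for all 5.

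Hepatocyte, pancreatic and adipocyte transcripts differed between libraries, also within a state. By list means, the largest difference between replicates exceeded that between state means in 0 of 3 lists (5.34 and 5.57 for hepatocyte markers), and by list medians in 3 of 3 (5.86 and 5.54). The physiological state gives no difference between replicates of one state, and for the differences between states it cannot be told apart from differences between samples, since the outcome turned with the summary and each state had 2 libraries. An open candidate explanation is tissue of neighbouring organs carried into some spleen samples. In the state whose replicates differed most, 95.3% of list members with a value of 5 or more followed their list, but that state was picked by the list's own median and members would move together under any common cause, so this share decides nothing.

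Ribosomal protein, respiratory chain and proteasome transcripts lay lower in arousal than in torpor. Across genes, not independent replicates, the arousal difference correlated with gene span (Spearman 0.426), and replicate differences, of arbitrary sign, did so at -0.248 in torpor, -0.241 in winter active, 0.0972 in arousal and -0.045 in summer. Without the trend on log gene span, camera still called 3 of 3 lists, with medians moving from -0.69 to -0.52, -0.47 to -0.40 and -0.28 to -0.28, arguing against this trend as the whole cause. Leaving out each torpor or arousal library ended 0 of the 12 calls, which argues against 1 library alone, though the median was -0.29 for respiratory chain genes without arousal 1, -0.13 for proteasome genes without torpor 1 and -0.18 for proteasome genes without arousal 1 and with an estimated correlation no call held (adjusted p = 0.85). RNA quality and the state itself may each contribute and were not tested.

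Erythroid transcripts lay lower in the November states than in summer. Column scaling by abundant globins moves all genes alike. In winter active against summer active, all 21 non-globin erythroid genes lay below the all-gene median, their median at -3.47 from it. This restates the list's camera call. Against mature red cells of residual blood alone, the early erythroid genes EPOR, KLF1, TFRC, GATA1, TAL1 and GFI1B had a median difference of -2.19. Only KLF1 (-3.48, limma adjusted p = 0.0403) and TAL1 (-2.13, 0.0342) passed, and EPOR differed by -0.54. These genes, picked after the erythroid fall was seen and not kept apart from its list, are no independent test. A lower share of erythroid precursors in the November spleen is a candidate explanation, and season, sampling month and state stay open and untested.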

How the results depend on the processing

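Rescaling to 1000000 was chosen after seeing the data. Fits without 1 library gave counts of 9 to 314 for torpor against summer, 0 to 2 for arousal against torpor, 0 for winter active against torpor, 15 to 382 for winter active against summer, 26 to 688 for arousal against summer, 0 to 1 for winter active against arousal, 16 to 190 for the F test and 0 to 1 for transient genes. With no filter, counts were 4 for winter active against torpor, 284 for arousal against summer, 1 for winter active against arousal and 40 for the F test. After rescaling, counts were 445 for arousal against torpor, 779 for winter active against summer, 6099 for arousal against summer and 2977 for the F test. In a fit of the 2 states alone, counts were 11 for torpor against summer, 32 for winter active against summer and 27 for arousal against summer. Fewer libraries, or more genes with no filter, accompany these changes. As 4 globin loci held 29.9% and 29.5% of summer totals and at most 3.13% elsewhere, equal totals raise other genes against summer. Further causes were not tested. Other settings but the replicate block moved no count by over 1.5 times. The unknown depth limits what low values show.

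With a replicate block, counts were 85 for torpor, 103 for winter active and 842 for arousal against summer, and 0 for each comparison within November. The F test called 46, 7 of the 103 were higher, and 56 genes were lower and 2 higher in all 3 November states. With adjusted p in brackets, the block ended the calls of interferon-stimulated genes in winter active against torpor (0.0514), erythroid markers in winter active against arousal (0.0542) and ribosome biogenesis genes in winter active against arousal (0.0542). Of named genes it ended those of LPCAT2 in torpor against summer (0.0655) and STEAP2, STEAP1, RHOJ and EIF2AK2 in winter active against summer (0.0548 to 0.0694). Deviations of same-numbered libraries correlated between states at -0.191 to 0.322, so the numbers do not pair the samples.

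Of 97 list calls, 43 held in all 8 fits without a library, and of 38 calls of named genes 10 did. Lists past the threshold in neither setting are given no direction. Adjusted p-values of lists whose direction turned follow. Under quantile normalization these were ribosomal protein genes 0.919 in winter active against torpor. After rescaling to 1000000 these were proteasome genes 0.752 in winter active against summer and hepatocyte markers 0.932 in arousal against summer. Over fits without 1 library, ranges of results that turned were hepatocyte markers 1.50e-05 to 0.785 and ribosomal protein genes 0.00714 to 0.938 in torpor against summer, then macrophage markers 2.55e-08 to 0.493 and endothelial markers 2.62e-06 to 0.533 in winter active against summer, then hepatocyte markers 2.11e-06 to 0.891 in arousal against summer, then neutrophil markers 1.19e-12 to 0.722 and pancreatic markers 3.70e-11 to 0.623 in arousal against torpor, then neutrophil markers 4.12e-14 to 0.814 and interferon-stimulated genes 2.87e-09 to 0.39 in winter active against torpor, then pancreatic markers 2.41e-15 to 0.294 in winter active against arousal. Log2 differences of genes whose sign turned, none past the threshold, follow. After rescaling to 1000000 these were CIRBP 0.15 and HSPA5 0.14 in torpor against summer. In arousal against torpor they were RBM3 0.047, FOS 0.11 and HMOX1 0.17, and in winter active against torpor RBM3 0.13. In winter active against summer they were SRSF2 0.11, ATP5MC3 0.10, NDUFA2 0.15, ADRM1 0.14, PSMD4 0.13 and PSMD13 0.19. Under quantile normalization these were HMOX1 0.38 in arousal against torpor, RBM3 0.089 in winter active against torpor and PER1 -0.031 in winter active against summer. Under median-of-ratios rescaling these were PER1 -0.012 in winter active against summer. Over fits without 1 library, ranges of results that turned were HSPA8 -0.11 to 0.36 and S100A8 -0.71 to 2.46 in torpor against summer, then CLPS -4.29 to 0.029, HSPA8 -0.18 to 0.46, FOS -0.48 to 0.063, MKI67 -1.08 to 0.39, S100A8 -2.87 to 0.30 and HMOX1 -1.01 to 0.59 in arousal against torpor, then RBM3 -0.10 to 0.0062 in winter active against torpor, then EGR1 -0.043 to 1.02, PER1 -0.29 to 0.36, FKBP5 -0.20 to 0.53 and HMOX1 -0.065 to 1.78 in winter active against summer. The cause was not tested.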

Other observations

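The genes in this part were chosen after their values were seen. The stomach genes GKN2, PGC and ATP4B stood at 594, 455 and 92.9 in winter active 2, and at 15.8, 89.5 and 2.12 in torpor 2. TFF2 stood at 126 in winter active 2, 72.2 in torpor 1 and 22.9 in arousal 2. The squamous genes KRT78, CNFN and S100A14 stood at 183, 116 and 312 in summer active 2 and at 0.082, 0 (listed at 0) and 0.735 in summer active 1. The insulin gene INS reached 201 in torpor 1 and at most 3.66 elsewhere.

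Camera called 9 of the 40 lists in none of the 6 comparisons. Their smallest camera adjusted p-values were 0.0732 for integrated stress response, 0.485 for p53 targets, 0.431 for mast cell and basophil markers, 0.107 for stromal and smooth muscle markers, 0.442 for complement, 0.485 for glycolysis, 0.323 for cholesterol synthesis and uptake, 0.179 for hypoxia (HIF) targets and 0.655 for autophagy.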
